A study of Mus musculus with 3 samples.

How the data were processed

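Ovaries of C57BL/6 female mice at embryonic day 16.5, postnatal day 7 and postnatal day 14 were digested with collagenase, passed through a 40 μm filter and loaded on the Chromium droplet system, per the labels. Its 3′ kit tags each captured mRNA with a cell barcode and a UMI near the polyadenylated end, so that UMIs, not reads, are counted. Each age is 1 library and all 3 were sequenced together on a single HiSeq lane, per the labels, so no sequencing batch separates them. The deposited files hold raw UMI counts per gene and cell barcode, made with Cell Ranger 2.1.1 on the GRCm38 build, per the submitters' processing notes. The gene annotation and the settings by which barcodes were called cells are not given in the sources used here. The barcodes had been filtered before deposit: the lowest totals were 6747, 6291 and 5568 UMIs at the 3 ages. The 3 tables list the same 53465 genes, by versioned Ensembl identifier and symbol, and 108 symbols are shared by several identifiers, whose levels are uncertain. Of these identifiers 50604 match GENCODE M21 (GRCm38) with the version and 53274 without it; positions of Esr1 and Esr2 come from that annotation.

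Cells with at least 200 detected genes and at most 20% mitochondrial UMIs were kept, 1548 of 1554 barcodes; 3, 1 and 2 cells were removed, all for few genes. The median mitochondrial share was 1.05%, 0.989% and 0.937%, and the median cell had 3667, 3696.5 and 3332 detected genes. The kept cells of all libraries were clustered together. Counts were scaled to 10000 UMIs per cell and log-transformed, the 2000 most variable genes were reduced to 30 principal components, and a graph of 15 nearest neighbours was split by the Leiden algorithm at resolution 1.0. Genes of the fixed lists were left out of the variable genes, so that the receptors and list members did not shape the clusters directly. Other genes that vary with them stayed in, and cluster 3 was led by mitotic genes. This gave 19 clusters. Markers of 9 cell classes (113 genes) named them: granulosa, surface epithelium or mesothelium, stroma, theca or steroidogenic, smooth muscle or pericyte, endothelium, germ cell, immune and erythroid. A cluster took the name of the class with most markers at least 2-fold above the other cells, if there were at least 3, if at least 1 was among the 10 leading genes (30 or more UMIs) and if no other class had more there. This threshold was not among the choices made in advance; 17 clusters were named and 2 were not, and their shares are reported by number. In granulosa-like cells the 20 granulosa markers summed to 5935, 6076 and 5747 CPM at the 3 ages. Different markers carried this sum. Between embryonic day 16.5 and postnatal day 7, Serpine2 went from 13.7 to 1331 CPM and Gng13 from 543 to 9.63 CPM, while Foxl2 went from 178 to 324 CPM. The steady sum thus does not show a constant cell state.

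Cells are not replicates, so the UMIs of each class were summed per library, scaled to 1000000 UMIs (CPM) and given with exact Poisson 95% intervals. Granulosa-like cells summed to 1826238, 1972317 and 1658830 UMIs, for which a count of 0 allows 3 UMIs, or 1.64, 1.52 and 1.81 CPM. Ratios of CPM have exact conditional binomial intervals, and shares exact Clopper-Pearson ones. No p-value or standard error was computed. To compare shares of cells with a UMI across depths, every cell was thinned at random to 5000 UMIs; 0 cells were shallower.

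The comparisons, the markers, 17 gene lists with 254 genes (253 in the tables), the rule for named genes and most alternatives were fixed before the data were examined. The lists are steroid receptors, follicle hormone and growth genes, embryonic ovary WNT genes, oestrogen response genes, receptor coregulators, Notch pathway, Hedgehog response genes, cell cycle S phase, cell cycle G2 and M phase, cyclin kinase inhibitors, imprinted growth genes, cholesterol synthesis and uptake, TGF-β family signalling, basement membrane and matrix, dissociation stress genes, germ meiotic prophase genes and germ oocyte growth genes. For each list the median log2 ratio of (CPM + 10) was taken over members with at least 10 UMIs in both libraries together. Members at least 2-fold apart are counted on that scale, which understates the change of low genes, while folds of single genes are ratios of CPM. The median's percentile among 10000 random lists of the same size, matched in 20 bins of mean CPM, describes these libraries and is no test across animals. The rule for named genes took, per contrast and direction, the 12 granulosa genes with the largest log2 ratio (5 in other classes with at least 20 cells at both ages). They needed 50 or more UMIs at the higher age, intervals that do not overlap and a level of at least 1 in 5 of the highest class in that library. Mitochondrial, ribosomal protein, haemoglobin, Xist and predicted genes were left out. Added to them were Esr1, Esr2, Foxl2, Amh, Lgr5, Cyp19a1 and Fshr, and the members at both ends of each list, which are listed for the contrasts of adjacent ages; further list members named as examples were chosen after their values were seen. Some genes that the rule took are not reported here.

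Doublets were called with Scrublet in Scanpy, which marked 1, 3 and 2 cells (0.219%, 0.589% and 0.343%), and were left in. Alternatives were a stricter cell filter (1000 genes, 10% mitochondrial UMIs), all deposited barcodes, Leiden resolutions 0.5 and 2.0, list genes kept in the clustering, each library clustered on its own, doublets removed, all cells with a Foxl2 UMI in place of the granulosa-like clusters, the mean of CPM over cells, scaling by the median ratio of genes, pseudocounts of 1 and 50 CPM, no low count filter or one of 30 UMIs, and thinning to 2000 UMIs or none. Chosen after seeing the data were granulosa-like cells without Upk3b or Upk1b UMIs, the main granulosa-like cluster of each library only, and stroma-like cells with clusters 3 and 5 added. Scaling by the median ratio moved log2 ratios by 0.062, 0.014 and 0.076 for postnatal day 7 against embryonic day 16.5, postnatal day 14 against 7, and postnatal day 14 against embryonic day 16.5.

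The steps were tested on simulated data. Counts were drawn from the libraries' means for 5176, 4462 and 4770 genes in the same 3 contrasts, with 200 genes changed in each. Of the genes changed 2-fold 98.5%, 98.5% and 97.0% were recovered, and 100% of those changed 4-fold or 8-fold; 0.583%, 0.540% and 0.766% of unchanged genes passed. Intervals held the true ratio for 94.5%, 95.0% and 94.5% of the changed genes. The draws were Poisson, so such coverage was built in. Only genes with at least 50 expected UMIs at both ages entered. Genes as low as Esr1 and uneven levels among cells were thus not covered. Of 100 unchanged lists 5%, 4% and 5% fell outside the range of the random lists. When 1266 cells were redrawn from their class means (25448 genes), 97.2% were given the right class, and 100% of the 269 granulosa-like cells. Redrawn cells of a class differed by counting error only, and the 282 cells of unnamed clusters were left out. The work used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, Scanpy 1.11.5, leidenalg 0.10.2, python-igraph 0.11.9 and Matplotlib 3.10.9.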

Results

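Gene expression was measured in single cells of whole ovaries from C57BL/6 female mice, with 1 library at each of 3 ages. The ages were embryonic day 16.5 (the title of that library says day 17), postnatal day 7 and postnatal day 14. The series title is about oestrogen receptors α (gene Esr1) and β (gene Esr2) in the granulosa lineage, the somatic cells that enclose and nourish the oocyte, so the balance of both mRNAs at each age is the main question. The deposited tables held 459, 510 and 585 cell barcodes at the 3 ages in that order, of which 456, 509 and 583 were kept. The total counts of unique molecular identifiers (UMIs, each standing for a captured mRNA molecule) over all barcodes were 8994085, 8743797 and 9065595. The median cell held 14877 UMIs at embryonic day 16.5, 12213 at postnatal day 7 and 11429 at postnatal day 14. Since each age has 1 library, no difference between ages has a replicate check and none was tested; all intervals are exact 95% intervals that cover counting error only. Levels are the UMIs of the summed cells of a class, scaled to a total of 1000000 (CPM).

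Granulosa-like cells made up similar shares of the 3 libraries, while blood cells, germ cells and stroma did not. There were 86 granulosa-like cells at embryonic day 16.5 (18.9% of the cells kept; 15.4 to 22.8), 89 at postnatal day 7 (17.5%; 14.3 to 21.1) and 94 at postnatal day 14 (16.1%; 13.2 to 19.4). Erythroid-like cells took 37.1% of the embryonic library (169 of 456 cells) and 3.14% and 1.72% of the postnatal ones. All shares are parts of the same total, so these cells lower the others in the embryo. Among the cells that were not erythroid-like, the granulosa-like share was higher in the embryo than after birth. Germ-cell-like cells took 15.1%, 2.36% and 0.515%, and the postnatal ones were large, with a median of 81812.5 UMIs at postnatal day 7 against 14282 in the embryo. Stroma-like cells took 23.0%, 39.3% and 37.2%. Theca-like cells, the androgen-making cells around the follicle, were found at postnatal day 14 (40 cells, 6.86%) and made 0 of 456 and 0 of 509 cells at the earlier ages. Endothelium-like cells numbered 18, 21 and 27, smooth-muscle-like cells 0, 11 and 24, immune-like cells 5, 15 and 8, and surface-epithelium-like cells 1, 14 and 12. Another 282 cells in 2 clusters met no class: cluster 3, led by Pimreg, Tubb6 and Mxd3, held 0.658%, 18.9% and 9.61% of the libraries, and cluster 5, led by Tmem100, Hhip and Osr2, held 0%, 6.88% and 15.8%. The tissue went through collagenase and a 40 μm filter before capture, which can set all of these shares.

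**Figure D1:**
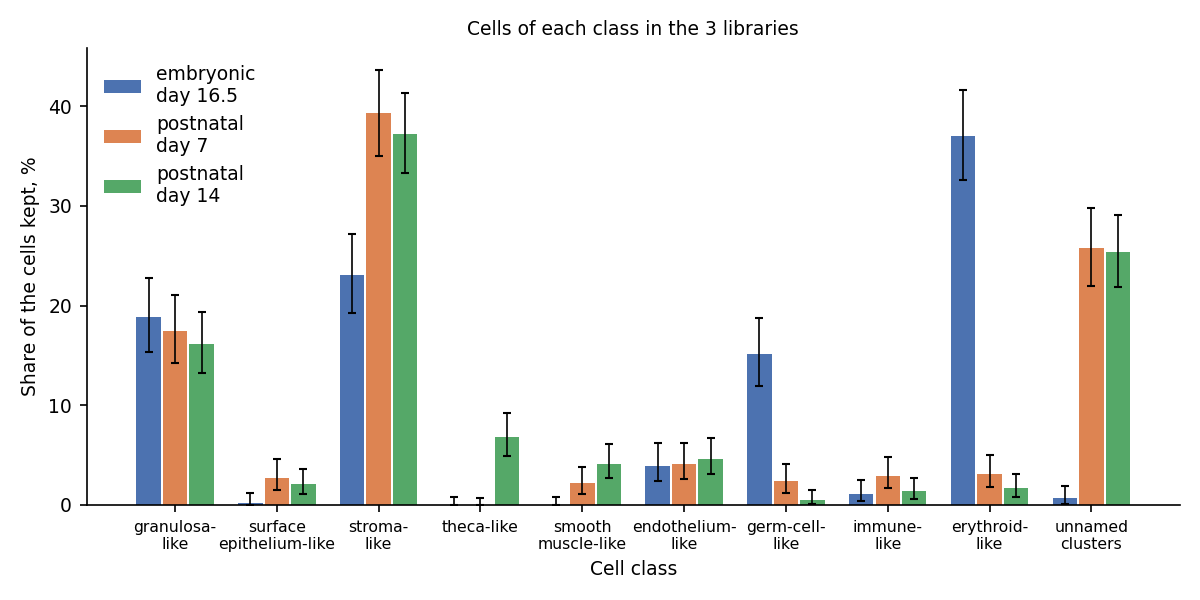
Share of the cells kept (%, vertical axis) in each cell class (horizontal axis) in the 3 libraries (colours); error bars are exact 95% binomial intervals. The granulosa-like share lay between 16.1% and 18.9%, and the erythroid-like share was 37.1% at embryonic day 16.5 and 1.72% at postnatal day 14.

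Esr2 was undetected in embryonic granulosa-like cells and was the more abundant receptor mRNA after birth. Of the summed Esr1 and Esr2 UMIs, Esr2 made 0% at embryonic day 16.5 (0 of 44; interval 0 to 8.04), 79.4% at postnatal day 7 (158 of 199; 73.1 to 84.8) and 89.0% at postnatal day 14 (130 of 146; 82.8 to 93.6). The Esr2 level was 0 CPM (upper bound 2.02), 80.1 CPM (68.1 to 93.6) and 78.4 CPM (65.5 to 93.1). It was thus at least 39.2-fold higher at postnatal day 7 and at least 38.2-fold higher at postnatal day 14 than in the embryo by the exact bound (48.8-fold and 47.7-fold against a floor of 3 UMIs), and the ratio of the postnatal ages was 0.978 (0.770 to 1.24). Esr1 stood at 24.1 CPM (17.5 to 32.3), 20.8 CPM (14.9 to 28.2) and 9.65 CPM (5.51 to 15.7), from 44, 41 and 16 UMIs. Its ratio of postnatal day 7 to embryonic day 16.5 was 0.863 (0.550 to 1.35), so that no difference was detectable at this depth. At postnatal day 14 it was 2.16-fold lower than at postnatal day 7 (1.18 to 4.11) and 2.5-fold lower than in the embryo (1.38 to 4.74).

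The tables name Esr1 as ENSMUSG00000019768.16 and Esr2 as ENSMUSG00000021055.14. In the GRCm38 annotation GENCODE M21, Esr1 is a protein-coding gene on chromosome 10, 4611593 to 5005614, plus strand, with no overlapping gene. Esr2 is a protein-coding gene on chromosome 12, 76120419 to 76177259, minus strand, and the processed pseudogene Gm7862 lies within it on the same strand, at 76152336 to 76152627.

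**Figure D2:**
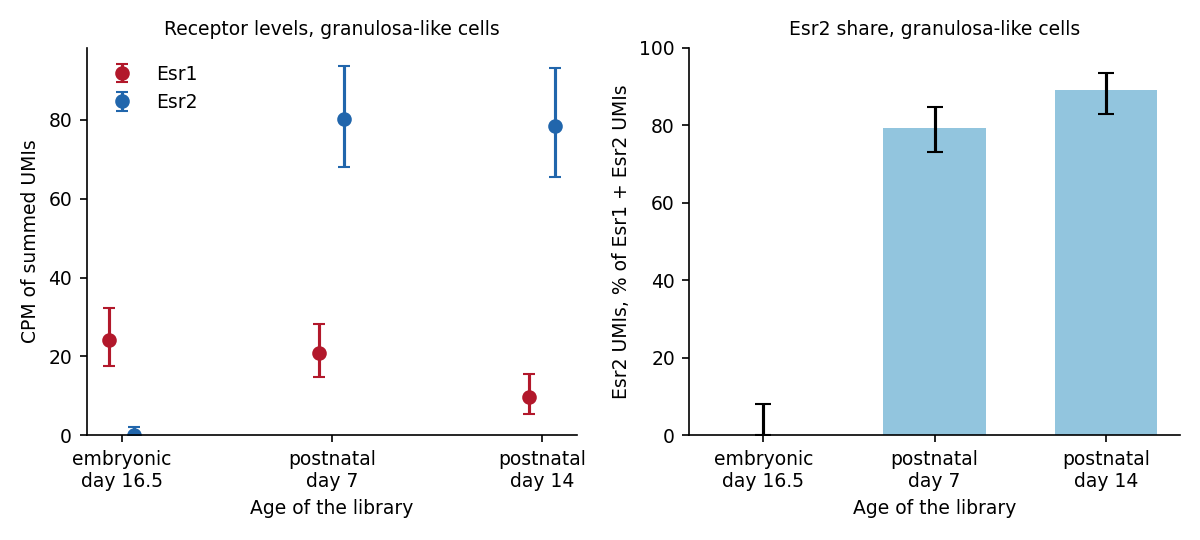
Left, Esr1 and Esr2 levels (CPM of summed UMIs, points) in granulosa-like cells at the 3 ages; right, Esr2 UMIs as a percentage of Esr1 plus Esr2 UMIs (bars); error bars are exact 95% counting intervals. Esr2 was at 0, 80.1 and 78.4 CPM and Esr1 at 24.1, 20.8 and 9.65 CPM.

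Different clusters held the granulosa-like cells of the 3 ages: cluster 9 in the embryo (86 cells), cluster 7 at postnatal day 7 (85 cells) and cluster 8 at postnatal day 14 (84 cells). At postnatal day 14 the other 10 cells lay in cluster 7, where Esr1 was at 44.3 CPM (17.8 to 91.3) and Esr2 at 38.0 CPM (13.9 to 82.7). In cluster 8 of the same library Esr1 was at 6.00 CPM (2.74 to 11.4) and Esr2 at 82.6 CPM (68.7 to 98.5). In the embryo, 68 cells without a UMI of the surface epithelium genes Upk3b and Upk1b held Esr1 at 17.2 CPM, and the mean over cells of each cell's Esr1 CPM was 15.5. Few cells carried the Esr1 UMIs: 22, 22 and 11 cells at the 3 ages, of which the 3 highest held 14, 15 and 8 UMIs. When each library was clustered on its own, Esr1 at postnatal day 14 came to 20.2 CPM, its difference from postnatal day 7 ended (log2 ratio −0.018) and that from the embryo came to −0.29; 3 of those 96 cells were germ-cell-like in the joint clustering and held 21 of the 37 UMIs. When all cells with a Foxl2 UMI were taken instead (827 cells, 239 of them granulosa-like), the Esr2 share was 49.1% and 64.1% at the postnatal ages, with Esr2 at 32.1 and 30.6 CPM and Esr1 at 33.3 and 17.1 CPM. The Esr1 log2 ratio against the embryo was then 0.80 and −0.17 in place of −0.21 and −1.32. Without cells that hold a Upk3b or Upk1b UMI it was 0.28 and −0.69, and in the main cluster of each library −0.17 and −2.01.

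Counted by cell from the same UMIs, Esr2 was found in granulosa-like cells at both postnatal ages and in none at embryonic day 16.5. With every cell thinned to 5000 UMIs, 0 of 86 granulosa-like cells had an Esr2 UMI in the embryo (which allows up to 3.49% by 3 cells of 86, with an exact upper bound of 4.20%), against 23.6% at postnatal day 7 (15.2 to 33.8) and 31.9% at postnatal day 14 (22.7 to 42.3). An Esr1 UMI was found in 9.30% (4.10 to 17.5), 5.62% (1.85 to 12.6) and 2.13% (0.259 to 7.48). Without thinning the Esr2 shares were 0%, 69.7% and 64.9% and the Esr1 shares 25.6%, 24.7% and 11.7%, at median depths of 17741.5, 17621 and 12496 UMIs. Endothelium-like cells were taken to lack both genes, which was not checked. They were compared apart from the planned background of germ-cell-like, immune-like and erythroid-like cells, at median depths of 22773, 23381 and 20983 UMIs. Thinned, they had Esr1 in 0 of 18, 0 of 21 and 0 of 27 cells (exact upper bounds 18.5%, 16.1% and 12.8%), and Esr2 in 0%, 0% and 3.70%. Unthinned, they had Esr1 in 0%, 0% and 7.41% and Esr2 in 0%, 4.76% and 14.8%. Erythroid-like and immune-like cells together (median depths 16399, 11843 and 16503) had Esr1 in 0 of 174, 2 of 31 and 0 of 18 thinned cells and Esr2 in 0 of each. Germ-cell-like cells were part of the planned background, but 5 of 12 had Esr1 at postnatal day 7 after thinning, so they are given apart; in the embryo it was 1 of 69. With so few background cells after birth, these shares do not place Esr1 of granulosa-like cells above or below background. By summed level, the Esr1 lower bound in granulosa-like cells lay above the endothelium-like upper bound in the embryo (17.5 against 7.62 CPM) and at postnatal day 7 (14.9 against 7.29 CPM), but not at postnatal day 14 (5.51 against 11.2 CPM). Immune-like cells, part of the planned background, held Esr1 at 27.2 CPM (11.7 to 53.6) at postnatal day 7 and germ-cell-like cells at 110.9 CPM, not below the granulosa-like level, and 16.1% of unthinned erythroid-like and immune-like cells had it.

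Cells with both receptors were about as many as the separate shares give. Unthinned, 17 of 89 granulosa-like cells had both at postnatal day 7 (19.1%; 15.3 cells expected) and 7 of 94 at postnatal day 14 (7.45%; 7.14 expected). Thinned, there was 1 such cell at postnatal day 7 (1.18 expected) and 0 at postnatal day 14 (0.638 expected). Amh, anti-Müllerian hormone, is made by granulosa cells of growing follicles. The Esr2 share was 83.1% (75.7 to 89.0) in the 65 cells with an Amh UMI after thinning and 71.4% (58.7 to 82.1) in the 24 without at postnatal day 7. At postnatal day 14 it was 91.1% (83.2 to 96.1) in 59 cells and 85.7% (73.8 to 93.6) in 35. The intervals overlap at both ages, and with Amh called at 2000 UMIs the order turned at postnatal day 7, to 76.3% with and 82.1% without, and at postnatal day 14, to 88.7% and 89.2%. Without thinning it was 81.8% and 60.9% at postnatal day 7 and 88.9% and 89.7% at postnatal day 14.

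Outside the granulosa-like cells, Esr2 was also found in postnatal stroma and in smaller classes, and Esr1 was spread over several classes. In stroma-like cells Esr2 was at 0.532 CPM in the embryo (1 UMI), 15.9 CPM at postnatal day 7 (11.0 to 22.4) and 29.5 CPM at postnatal day 14 (22.9 to 37.4), a ratio of 1.85 between the last ages (1.21 to 2.90). Esr1 in the same cells was at 14.9 CPM (9.89 to 21.5), 16.9 CPM (11.8 to 23.5) and 13.5 CPM (9.14 to 19.1). These cells came from cluster 6 in the embryo, mostly from cluster 1 at postnatal day 7 (186 of 200) and mostly from cluster 2 at postnatal day 14 (184 of 217). Within cluster 1 Esr2 was at 13.3 CPM (8.61 to 19.6) and 35.9 CPM (16.4 to 68.2) at these ages, and within cluster 2, the other way, at 44.5 CPM (19.2 to 87.7) and 29.7 CPM (22.6 to 38.3), so the ratio of the ages is also one of clusters. An Esr2 UMI was found in 0%, 8.0% and 14.3% of thinned stroma-like cells (unthinned 0.952%, 13.5% and 24.0%; median depths 12612, 8205 and 8479). Theca-like cells at postnatal day 14 had Esr1 at 30.9 CPM (20.4 to 44.9) and Esr2 at 1.14 CPM (1 UMI). Esr2 was also at 30.2 CPM (9.82 to 70.5) and 19.1 CPM (6.20 to 44.5) in smooth-muscle-like cells at postnatal days 7 and 14, from 5 UMIs each, and at 18.0 CPM (10.5 to 28.8; 17 UMIs) in germ-cell-like cells at postnatal day 7. Endothelium-like cells had Esr1 at 0, 0 and 3.09 CPM (0.374 to 11.2 at postnatal day 14), an interval that overlaps that of granulosa-like cells at the same age. Foxl2, a transcription factor that maintains granulosa identity, was in stroma-like cells too, at 35.1, 176 and 158 CPM.

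**Figure D3:**
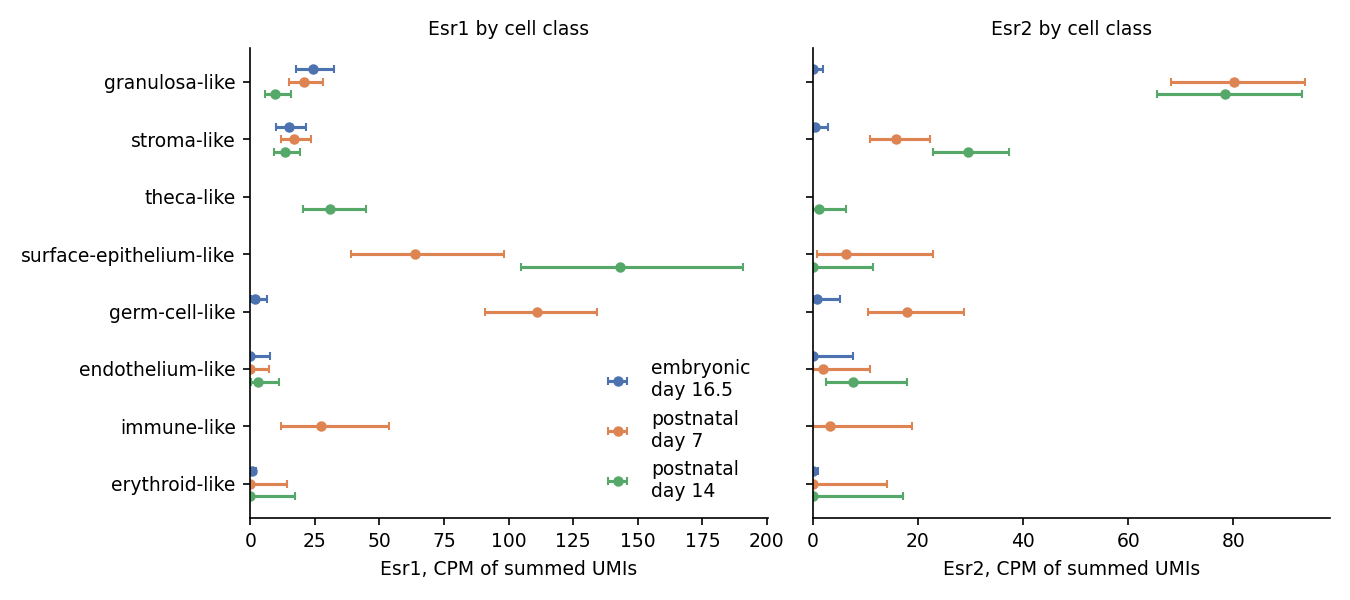
Esr1 (left) and Esr2 (right) levels (CPM of summed UMIs, horizontal axes, different scales) by cell class and age for classes of at least 10 cells; error bars are exact 95% counting intervals. Esr2 reached 80.1 CPM in granulosa-like and 29.5 CPM in stroma-like cells, and Esr1 reached 143 CPM in surface-epithelium-like cells of postnatal day 14 (12 cells).

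Between embryonic day 16.5 and postnatal day 7, granulosa-like cells (clusters 9 and 7) differed most in follicle hormones, embryonic ovary WNT genes, imprinted genes and mitotic genes. Follicle hormone and growth genes were higher: 9 of 13 measured members by at least 2-fold and 0 lower, with a median log2 ratio of 1.43 that lay at percentile 100 of 10000 random lists matched on level. Amh was at 478 against 1.10 CPM (2 UMIs in the embryo; 436-fold, 120 to 3606), Inha, the α subunit of inhibin, at 1364 against 99.1 CPM (13.8-fold), Inhbb at 227 against 37.2 CPM and the gap junction gene Gja1 at 352 CPM (3.61-fold). Embryonic ovary WNT genes were lower, 9 of 14 by at least 2-fold and 0 higher (median −1.41, percentile 0). That list, also called WNT genes here, is mixed. Beside WNT pathway genes it holds the transcription factor genes Emx2, Lhx9, Lhx2, Gata4 and Gata2. Its median is thus no measure of WNT signalling alone. Lgr5, a receptor for R-spondins, was 36.7-fold lower (15.4 to 115, at 93.1 and 2.54 CPM) and the WNT target Sp5 27.5-fold lower. Rspo1, which encodes an R-spondin, was 6.47-fold lower, and of the transcription factor genes Lhx9 was 9.81-fold lower. Of the other genes fixed for every library, Foxl2 was at 178 and 324 CPM (1.82-fold higher; 1.59 to 2.09), the aromatase gene Cyp19a1 at 1.64 and 5.07 CPM, and Fshr, the receptor of follicle-stimulating hormone, at 0 and 1 UMI.

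Genes of mitosis were higher at postnatal day 7 and cyclin kinase inhibitors lower. In the G2 and M phase list 16 of 20 genes were at least 2-fold higher and 0 lower (median 1.29, percentile 100), among them Ccnb2 (5.23-fold), Ube2c (4.10-fold) and Mki67 (2.64-fold). The S phase list had a median of 0.55 (percentile 99.99), with 1 of 18 genes, Uhrf1, past 2-fold (3.67-fold). Of 6 cyclin kinase inhibitors, 2 were lower and 0 higher (median −0.80, percentile 0.04): Cdkn1c, which restrains growth and is imprinted, was 88.9-fold lower (14.2 against 1262 CPM) and Cdkn1a 2.99-fold lower. Imprinted growth genes, which include Cdkn1c, were lower in 9 of 14 cases and higher in 1 (median −2.25, percentile 0). The noncoding H19 was at 33.5 against 2790 CPM (83.4-fold lower), Mest 21.5-fold, Peg10 18.0-fold and Dlk1 17.5-fold lower, while Plagl1 was 5.26-fold higher. H19 and Dlk1 also led the embryonic stroma cluster. Summed stroma markers in granulosa-like cells were at 20.5% of their own class's level in the embryo and 3.68% at postnatal day 7. H19 was lower in embryonic stroma-like cells (1619 CPM) than in granulosa-like ones. Dlk1 went the other way, at 864 CPM in embryonic stroma-like and 212.5 CPM in granulosa-like cells, so RNA from stroma stays open as a source of it.

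Notch pathway genes were higher in 4 of 10 cases and lower in 0 (median 0.67, percentile 100): the target genes Heyl (12.5-fold), Hey1 (5.99-fold) and Hey2 (9.41-fold), and Nrarp (14.2-fold, from 3 UMIs in the embryo). Oestrogen response genes were split, 3 of 13 higher and 3 lower (median 0.34, percentile 99.5; 0 without the filter on low counts). The cyclin gene Ccnd2 was 2.85-fold, Susd3 3.38-fold and Myc 5.05-fold higher, and the insulin-like growth factor binding protein genes Igfbp4 and Igfbp5 were 5.31-fold and 2.70-fold lower. Greb1 was at 186 against 91.4 CPM. In the TGF-β family list 3 of 19 were lower and 0 higher (median −0.43, percentile 0.60), all inhibitors of differentiation: Id2 was 5.55-fold, Id1 2.95-fold and Id3 2.18-fold lower. Of 7 measured steroid receptors, 2 were higher by 2-fold, with Esr2 at the top, and 0 lower; the median (−0.13, percentile 48.7) and the mean (0.68) differ in sign. Like that of the steroid receptors, the medians of the coregulator, Hedgehog, cholesterol, matrix and stress lists lay within the range of 95% of the random lists. Receptor coregulators had 0 of 16 past 2-fold (median −0.33, percentile 3.12), Hedgehog response genes 1 of 5 (Ptch1, 2.66-fold higher; median −0.40, mean 0.08), and cholesterol genes 2 of 20 lower (median −0.19). Matrix genes had 2 of 12 higher, Col18a1 and Lama1, and 1 lower, Fn1 (median 0.09). Dissociation stress genes had 2 of 15 higher and 2 lower (median −0.17, mean 0.18), with Hspa1a at 261 against 5.48 CPM. Members at the ends of their lists that are not named above were, by log2 ratio, Nr3c1 (−0.88) among steroid receptors, Nr5a1 (0.18) among follicle genes and Znrf3 (−0.07) among WNT genes. Among coregulators Ncoa1 (−0.81) was lowest. The Notch and Hedgehog lists ended at Notch3 (−0.77) and Smo (−0.55), and the cell cycle lists at Slbp (−0.22), Bub1 (0.24) and Cdkn2c (0.37). The cholesterol genes ended at Fdps (0.52) and Hmgcs1 (−1.42), the TGF-β list at Smad3 (0.85) and the stress list at Atf3 (−1.53). The counting intervals of both ages overlap for Nr5a1, Znrf3, Slbp, Bub1 and Cdkn2c.

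The germ meiotic list, counted in granulosa-like cells as a sign of RNA from other cells, was lower in 9 of 14 genes (median −1.09, or −1.05 with undetected genes at the floor), with Sycp1 at 0 against 50.4 CPM at one end and Msh5 (log2 ratio −0.36, overlapping intervals) at the other. Summed germ cell markers in granulosa-like cells moved the same way, from 6.08% of the germ-cell-like level in the embryo to 0.402%. The germ oocyte growth list had 1 gene higher and 1 lower of 8, Uchl1 (1.04) and Kit (−1.14; median 0.38, or 0.33 at the floor). Summed surface epithelium markers were at 2134, 735 and 371 CPM in granulosa-like cells at the 3 ages, of which Lgals7 made 971 CPM in the embryo, so they moved with the WNT and imprinted lists. Summed erythroid markers stood at 1.95%, 0.131% and 0.0537% of their own class, immune markers at 0.291%, 0.200% and 0.0820%, and endothelium markers at 1.34%, 0.504% and 5.61%. Smooth muscle markers came to 80.5, 38.5 and 145 CPM and theca markers to 567, 587 and 1203 CPM.

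By size alone, the rule for named genes took mostly list members, granulosa markers and genes that lead a cluster. The others higher at postnatal day 7 were Synpo, an actin-associated protein (232 against 7.67 CPM, 30.3-fold), the transporter gene Slco3a1 (38.1-fold) and Arhgap31 (12.9-fold). Higher in the embryo was Ifitm1, an interferon-induced membrane protein (660 against 60.3 CPM). Serpine2, Slc18a2, Hsd17b1, Nr5a2 and Gng13 were taken as markers of the class, and Ptges, Fam13a, Cma1, Dclk1 and AC131720.3 as genes that lead a granulosa-like cluster. For each gene of this paragraph the counting intervals of both ages lie apart. The sizes of the list medians depend on the pseudocount: with 50 CPM in place of 10 the follicle, WNT, Notch, G2 and M and imprinted medians came to 0.75, −0.64, 0.26, 0.61 and −1.36, with the directions kept. Among all cells with a Foxl2 UMI the follicle median was 0.76 and the imprinted median −1.04.

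**Figure D4:**
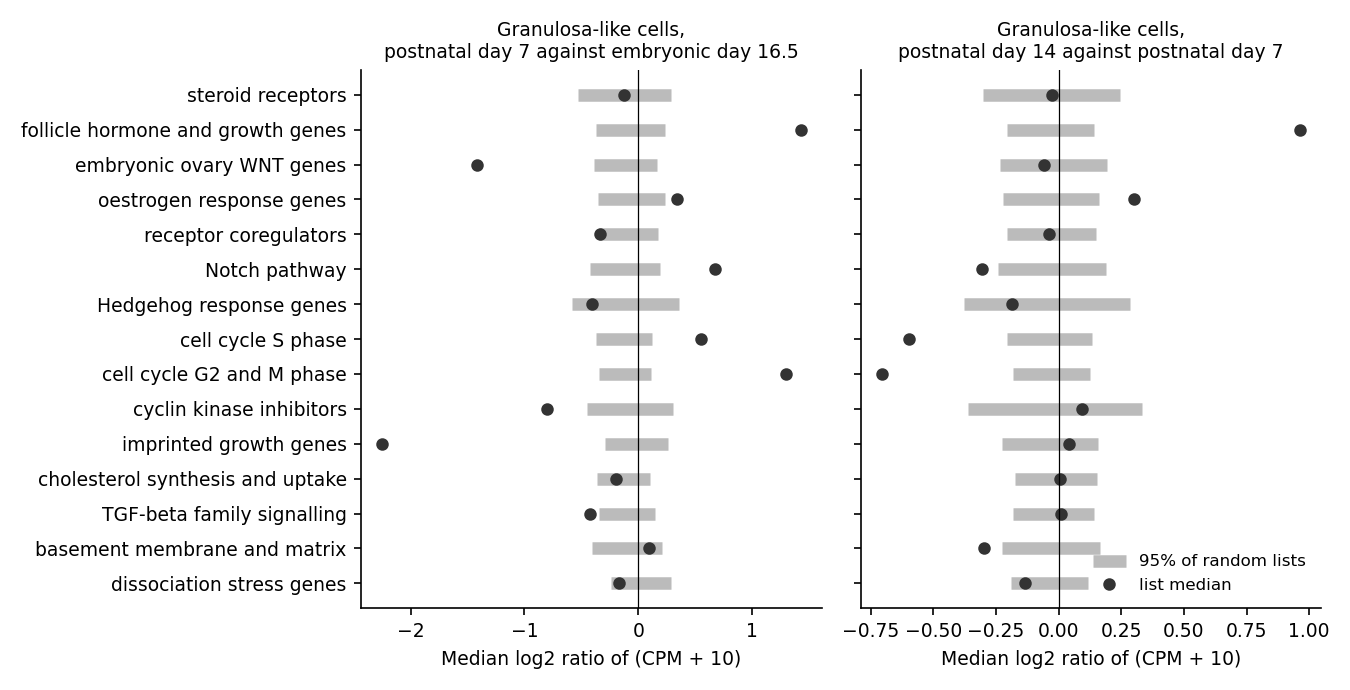
Median log2 ratio of (CPM + 10) of each gene list (points, horizontal axes, different scales) in granulosa-like cells, postnatal day 7 against embryonic day 16.5 (left) and postnatal day 14 against postnatal day 7 (right); grey bars span 95% of 10000 random lists of the same size and level. Follicle hormone genes lay to the right in both (1.43 and 0.97), and the G2 and M phase list lay to the right in the left panel (1.29) and to the left in the right panel (−0.71).

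From postnatal day 7 to postnatal day 14 (clusters 7 and 8), inhibin and other follicle genes were higher and cell cycle genes lower. Of 15 follicle hormone and growth genes, 7 were at least 2-fold higher and 0 lower (median 0.97, percentile 100). Inhba, the inhibin and activin βA subunit, was at 306 against 18.8 CPM (16.3-fold), Inha at 4346 against 1364 CPM (3.19-fold), Ihh, which encodes the signal Indian hedgehog, at 185 against 32.5 CPM (5.70-fold), and Gja1 2.21-fold higher. Fshr had 26 UMIs against 1 (30.9-fold; 5.08 to 1267), and Cyp19a1 was at 22.3 against 5.07 CPM (4.40-fold; 2.15 to 9.92). Amh (459 and 478 CPM) and Inhbb (246 and 227 CPM) were close at the 2 ages, as was Foxl2 (283 and 324 CPM). The G2 and M phase list had 3 of 20 genes lower by 2-fold and 0 higher (median −0.71, percentile 0) and the S phase list 0 of 18 either way (median −0.59, percentile 0); Mki67 was 2.25-fold lower.

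Among the signalling lists, the Notch targets Hey1 and Heyl were 5.75-fold and 4.18-fold lower, the 2 of 11 past 2-fold (median −0.31, percentile 0.67). Oestrogen response genes had 1 of 13 higher, Igfbp5 (3.98-fold), and 2 lower, Igf1 (3.88-fold) and Ccnd2 (2.61-fold); the median was 0.30 (percentile 99.96), with Greb1 at 353 against 186 CPM. That median was 0.053 without the filter on low counts and turned to −0.12 among all cells with a Foxl2 UMI. Of the WNT genes 1 of 11 was lower, Rspo1 (7.01-fold; median −0.06), and Lgr5 was at 0.603 CPM. Imprinted genes went both ways, with Meg3 (4.04-fold) and Peg10 (3.96-fold) higher and Peg3 (4.51-fold) and Plagl1 (2.20-fold) lower among 13 (median 0.04). Of 5 cyclin kinase inhibitors 1 was lower, Cdkn1b (3.24-fold; median 0.10, mean −0.32). Basement membrane and matrix genes had a median of −0.30 (percentile 0.52) with 0 of 12 past 2-fold, and 0.04 among all cells with a Foxl2 UMI. No member passed 2-fold among 7 steroid receptors (median −0.03), 15 coregulators (−0.04) and 5 Hedgehog response genes (−0.18). The same held for 19 TGF-β family genes (0.01) and 15 stress genes (−0.13). Of 20 cholesterol genes 1 did, Sqle, which was lower (median 0.01). Esr1 was the lowest steroid receptor, at −0.65 on this scale. Its counting intervals at both ages overlap, but the interval of its CPM ratio, 0.243 to 0.845, leaves out 1. Of the germ meiotic list 2 genes were measured, too few for a median. The germ oocyte growth list had a median of −0.55 over 6 genes (−0.44 at the floor), which turned to 1.99 when each library was clustered on its own.

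The other ends of the lists, by log2 ratio, were Pgrmc2 (0.20) among steroid receptors, Dhh (−0.25) among follicle genes and Znrf3 (0.33) among WNT genes. Ncoa2 (0.34) was the highest coregulator and Notch3 (0.70) the highest Notch gene, and Hedgehog genes ran from Smo (0.23) to Gli2 (−0.74). The S phase list ran from Slbp (−0.033) to Uhrf1 (−0.88), the G2 and M phase list from Cenpf (−0.20) to Cks2 (−1.03), and Cdkn1c (0.28) was the highest kinase inhibitor. Insig1 (0.59) was the highest cholesterol gene. The TGF-β list ran from Id3 (0.78) to Id1 (−0.67), the matrix list from Fn1 (1.00) to Lama1 (−0.69), the stress list from Jund (0.26) to Dusp1 (−0.89), the germ meiotic genes from Msh5 (−0.38) to Syce2 (−1.03) and the oocyte genes from Sohlh1 (−0.38) to Zp2 (−0.69). The counting intervals overlap for Pgrmc2, Dhh, Znrf3, Ncoa2, Smo, Slbp, Cenpf, Cdkn1c, Insig1, Msh5 and Sohlh1.

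The rule named further genes outside the lists. Higher at postnatal day 14 were the amino acid enzymes Cbs (71.1 CPM against 3 UMIs; 46.8-fold, log2 interval of the ratio 3.97 to 7.85) and Ass1 (86.2 against 5.58 CPM; 15.5-fold), Susd4, a complement regulator (8.72-fold), the noncoding Rian, a neighbour of Meg3 (5.42-fold), Otor (41.6 CPM against 1 UMI; log2 interval 3.83 to 11.7) and the mitochondrial carrier gene Slc25a35 (41.6 CPM against 3 UMIs; 3.17 to 7.09). Higher at postnatal day 7 were Tcea3 (9.49-fold), Ank1 (8.11-fold), the calcium-binding protein gene Calb1 (7.03-fold), Sel1l3 (5.89-fold), Tex14 (5.73-fold), the heparan sulphate enzyme gene Hs6st2 (5.02-fold), the class I histocompatibility gene H2-K1 (4.07-fold) and Sdc1, a syndecan (309 against 77.8 CPM; 3.98-fold). Siglece was at 37.5 CPM against 3 UMIs (20.8-fold; log2 interval −6.68 to −2.77). Nap1l5 was taken as a class marker and Car14, Krt79 and Nrn1 as genes that lead a cluster. Without the 10 cells of cluster 7 and the other cells outside each age's main cluster, the G2 and M phase median was −1.07, and with a pseudocount of 50 CPM the follicle and the G2 and M phase medians were 0.38 and −0.38.

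Across the whole span, postnatal day 14 against embryonic day 16.5, 13 of 15 follicle genes were at least 2-fold higher (median 1.81) and 9 of 14 WNT genes (median −1.45) and 8 of 14 imprinted genes (median −1.80) lower. Inha was 43.9-fold and Inhba 140-fold higher, and Fshr at least 7.22-fold higher by the exact bound (15.7 CPM against 0; 9.54-fold against a floor of 3 UMIs). Rspo1 was 45.3-fold lower and Peg3 15-fold lower. Of the cell cycle lists, S phase had a median of −0.01 and G2 and M phase 0.41 with 3 of 20 higher, a median that came to 0.022 among all cells with a Foxl2 UMI. Notch genes had a median of 0.50, oestrogen response genes 0.13 and cyclin kinase inhibitors −1.21. Socs2, a suppressor of cytokine signalling, was at 757 against 47.1 CPM (16.1-fold). Smpx was at 3 UMIs against 160 CPM in the embryo (88.4-fold lower; log2 interval −8.75 to −4.90), and the surface epithelium marker Lgals7 was 24.8-fold lower. The germ oocyte list had a median of −0.74, which turned to 1.06 among all cells with a Foxl2 UMI and to 2.17 when each library was clustered on its own; that of the germ meiotic list was −1.14. Undetected genes at the floor make these medians −0.71 and −0.98. The other lists had medians of −0.14 (steroid receptors), −0.32 (coregulators), −0.28 (Hedgehog), −0.27 (cholesterol), −0.32 (TGF-β), −0.01 (matrix) and 0.07 (stress).

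In stroma-like cells (cluster 6 in the embryo, then clusters 1 and 2) imprinted genes were lower after birth. Cell cycle genes were lower too in these clusters, but the size and for G2 and M phase genes at postnatal day 7 the direction depend on leaving out the unnamed clusters 3 and 5. The difference from granulosa-like cells was not tested. At postnatal day 7 against the embryo, 14 of 20 G2 and M phase genes and 7 of 18 S phase genes were at least 2-fold lower (medians −1.27 and −0.84), and 5 of 14 imprinted genes were lower (median −0.81). With clusters 3 and 5 added to the stroma-like cells, the G2 and M phase median turned to 0.81 and the S phase median came to −0.0053. At postnatal day 14 against the embryo these medians were −1.48 and −1.27 without those clusters and −0.097 and −0.64 with them. At postnatal day 7 against the embryo, matrix genes had a median of 0.59, steroid receptors 0.55, WNT genes −0.61 and cholesterol genes −0.68. Named by the rule in that contrast were Actr3b (221 against 3.72 CPM; 59.4-fold higher), Hspa1a, a heat shock gene of the stress list (37.1-fold higher), H19 (16.9-fold lower), Cd24a (9.02-fold lower), the potassium channel gene Kcnk3 (11.3-fold lower) and Crabp1, a retinoic acid binding protein (64.9 CPM against 3 UMIs; log2 interval −7.78 to −3.90). Fhl2, Mfap5 and Hist1h2ap were taken as genes that lead a cluster. From postnatal day 7 to postnatal day 14 imprinted genes were lower again (median −0.65, 6 of 13 by 2-fold), with Dlk1 at 752 and 36.9 CPM, H19 55.3-fold and Meg3 8.48-fold lower. Dissociation stress genes had a median of 0.26 (percentile 99.96) with 0 of 15 past 2-fold, and of 0.33 (percentile 99.93) with 3 higher at postnatal day 14 against the embryo. From postnatal day 7 to 14 the genes named as higher, Cxcl14, Spon1, Csmd1, Clec1a and Nupr1, lead a cluster, and Ptn and Postn are class markers.

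In endothelium-like cells (cluster 10 at both ages; 21 and 27 cells), the rule named the following genes as higher at postnatal day 14. Lyve1, a hyaluronan receptor, was at 139 CPM against 0 UMIs (lower bound of the log2 ratio 4.22), and Mmrn1 at 241 CPM against 1 UMI (122-fold; log2 interval 4.43 to 12.2). Ptx3 was at 130 CPM against 0 UMIs (lower bound 4.12), and the water channel gene Aqp1 was 20.2-fold higher. The chemokine gene Ccl21a had the largest difference, but its symbol is shared by several gene IDs and it leads the cluster, so its level is uncertain. Higher at postnatal day 7 were the chemokine gene Cxcl12 (7.96-fold), Gja4 (3.69-fold), Igfbp3 (3.47-fold), Gadd45g (3.34-fold) and the transcription factor gene Sox17 (2.67-fold). For the genes of both directions, whether all cells or a few of a distinct endothelial kind carried the UMIs was not examined. The differences may thus lie in the kinds of cells caught.

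In germ-cell-like cells meiotic genes took a lower share of the UMIs and oocyte growth genes a higher one after birth. These cells lay in clusters 11 and 18 in the embryo (69 cells) and in cluster 19 after birth, with 12 cells at postnatal day 7 and 3 at postnatal day 14, too few to compare list medians. At postnatal day 7 against the embryo, 16 of 16 meiotic genes were lower in CPM with intervals apart. Of 18 measured oocyte growth genes 17 were higher in CPM, and Sohlh2 (62.7 and 38.0 CPM) had overlapping intervals. Sycp1, of the synaptonemal complex, was at 922 CPM (865 to 981) in the embryo and 67.6 CPM (52.1 to 86.3) at postnatal day 7, and Stra8, needed to enter meiosis, at 633 CPM and 0. Syce2 (912 and 360 CPM) and Syce1 (255 and 118 CPM) were lower in CPM but still counted at postnatal day 7. The postnatal day 7 cells held more UMIs each, with a median of 81812.5 against 14282. Per cell, Syce2 (989 UMIs in 69 cells and 341 in 12), Syce1 (277 and 112) and Msh4 (30 and 9) were thus not lower. The other meiotic genes were lower per cell too. Zp3, a protein of the egg coat, was at 0.922 CPM (1 UMI) and 1409 CPM (1335 to 1487), Gdf9, an oocyte growth factor, at 0 and 340 CPM (304 to 379), and Figla, which activates egg coat genes, at 136 and 902 CPM.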

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

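Of the tests on explanations given here, the one on doublets of stroma and granulosa cells was set before its result was seen, and all others were chosen after.

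Classes too small for the comparisons held Esr1 above the endothelium-like level. Postnatal germ-cell-like cells, all in cluster 19, held 105 Esr1 UMIs in 12 cells at postnatal day 7 (110.9 CPM; 90.7 to 134) and 21 UMIs in 3 cells at postnatal day 14. Surface epithelium cells in the same droplets are argued against: their 13 summed markers were at 255 CPM, 2.88% of the level in surface-epithelium-like cells (upper bound 3.39%), with Lgals7 at 39.1 against 2502 CPM and Krt19 at 0 against 1313 CPM; 4 of the 13 reached 10 CPM and Wt1 made most of the sum. These cells also held granulosa genes, with Foxl2 at 88.7 against 324 CPM and Esr2 at 18.0 against 80.1 CPM in granulosa-like cells, which goes with some RNA of granulosa cells in them. Such cells or their free RNA as the whole source are argued against, since Esr1 was 5.34 times the granulosa-like level, with bounds 3.22-fold apart. Expression by growing oocytes may remain as a hypothesis, which the age of the animals does not separate from cell size or from other cells attached to oocytes.

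Esr2 was also found in postnatal stroma-like cells. Free RNA would carry Amh and Inha in the granulosa ratio, but these stood at 0.473% and 1.34% of the granulosa-like level at postnatal day 14, which predicts 1.05 CPM of Esr2 against 29.5 observed (lower bound 22.9). Doublets with granulosa cells that hold Amh and Inha are argued against too. The 52 stroma-like cells with an Esr2 UMI had Amh and Inha at 1.41% of that level (upper bound 1.93%). Neither comparison covers granulosa cells poor in both genes. At postnatal day 14, granulosa-like cells without an Amh UMI after thinning still had Esr2 at 75.3 CPM. A source in granulosa cells poor in both genes therefore stays open. Foxl2 does not decide it. It was at 158 CPM in stroma-like against 283 CPM in granulosa-like cells of that library. But it was also at 145 CPM in smooth-muscle-like cells and 92.1 CPM in cluster 3, with 44.6 CPM in theca-like and 18.5 CPM in endothelium-like cells. A stroma-like population with its own Esr2 is a candidate explanation that was found on the same data; the difference between ages has no replicate and sets mostly cluster 2 against cluster 1.

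Esr1 in embryonic granulosa-like cells rests on 44 UMIs. Free RNA is argued against by 0.779 CPM (upper bound 1.99) in 256 endothelium-like, erythroid-like and germ-cell-like cells of that library. Surface epithelium cells in the cluster stay open: the 68 cells without Upk3b or Upk1b UMIs had Esr1 at 17.2 CPM (lower bound 10.9; endothelium-like upper bound 7.62), but their summed surface markers were at 1845 CPM against 2929 CPM in the other 18, so the split leaves much of the surface signal in. Those 18 cells had 2.51 times that Esr1 level (1.32 to 4.74), with Foxl2 at 88.3 against 211 CPM and Lgr5 at 117 against 84.4 CPM, so part of the Esr1 may come from cells that share surface epithelium genes. Of the 13 surface markers 9 reached 10 CPM in embryonic granulosa-like cells, but Lgals7 (971 CPM) and Wt1 (499 CPM) made most of their sum of 2134 CPM. Set against surface-epithelium-like cells of postnatal day 7, Krt19 was at 49.8 against 1313 CPM and Upk3b at 63.5 against 909 CPM. Podxl was closer, at 200 against 340 CPM. The summed surface signal thus rests mainly on Lgals7 and Wt1. Mixed cells and cells of an intermediate type stay open.

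Surface-epithelium-like cells held 20 Esr1 UMIs at postnatal day 7 (14 cells, 63.6 CPM) and 46 at postnatal day 14 (12 cells, 143 CPM). Immune-like cells held 8 at postnatal day 7 (15 cells, 27.2 CPM; 11.7 to 53.6).

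Some cell cycle medians went opposite ways in granulosa-like and stroma-like cells, a difference that was not tested and that depends on the cells counted as stroma. At postnatal day 7 against embryonic day 16.5 the S phase medians were 0.55 and −0.84 and the G2 and M phase medians 1.29 and −1.27. At postnatal day 14 against embryonic day 16.5 the G2 and M phase medians were 0.41 and −1.48, and the S phase medians −0.01 and −1.27. At postnatal day 14 against 7 both classes went the same way, with S phase medians of −0.59 and −0.39 and G2 and M phase medians of −0.71 and −0.29. With the unnamed clusters 3 and 5 added to the stroma-like cells, for which stroma was the class with most markers and of which cluster 3 is led by mitotic genes, the stroma-like medians came to −0.0053 (S phase) and 0.81 (G2 and M phase) at postnatal day 7. The G2 and M phase median at postnatal day 14 against the embryo came to −0.097. Among all cells with a Foxl2 UMI the median set against it was 0.022 in place of 0.41.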

How the results depend on the processing

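The alternatives without Upk3b or Upk1b UMIs, with the main cluster of each library only and with clusters 3 and 5 added to stroma were chosen after the results were seen; the others were planned.

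With 1 library per age, leaving out a replicate and other splits of the samples could not be run. No paired analysis was possible because each age has 1 library. A level or share counts as moved outside its counting interval, and a list median when it shifts by more than the spread of its random lists. Of 1939 values of 158 results under the alternatives, 1723 stayed the same, 210 moved and 6 reversed, which means that the sign changed although the counting interval or spread excluded 0. Another 45 values changed sign where that interval or spread held 0, so that no direction had been called. For the receptors and cell shares 173 of 197 stayed and 0 reversed, for list medians 707 of 804 stayed and for named genes 841 of 936. The receptor values that changed sign without a call were Esr1 for postnatal day 7 against the embryo (0.80 and 0.28 in place of −0.21) and Esr2 for postnatal day 14 against 7 (0.023 and 0.0066 in place of −0.032). The other 41 were list medians. Of the 72 named genes, 71 were chosen again under other filters on low counts. The stricter cell filter, all barcodes, both Leiden resolutions and scaling by the median ratio moved no result, and removing doublets moved 1 named gene. The cell filters and resolutions shared 268 or 269 granulosa-like cells with the main choice, and the scaling shifted log2 ratios by at most 0.076. Little could move under them, and their values are among those counted as the same. Esr2 stayed at 0 CPM in the embryo under every clustering, and was 0.391 CPM among cells with a Foxl2 UMI. Depth limits Esr1, since 16 UMIs at postnatal day 14 set its interval of 5.51 to 15.7 CPM; other choices of cells gave 20.2 and 17.1 CPM, outside it. Except where fewer or other cells are named below, the cause of a move was not tested.

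Among all cells with a Foxl2 UMI, 827 cells of which 239 are granulosa-like, the Esr2 share was 49.1% and 64.1% at postnatal days 7 and 14, Esr1 33.3 and 17.1 CPM, and Esr2 32.1 and 30.6 CPM. The Esr1 log2 ratio was 0.80 for postnatal day 7 and −0.17 for postnatal day 14 against embryonic day 16.5. List medians for postnatal day 7 against embryonic day 16.5 were follicle 0.76, Hedgehog 0.18 (−0.40 before, not called), G2 and M 0.92, kinase inhibitors −0.32, imprinted −1.04, matrix 0.60, germ meiotic −0.74 and germ oocyte 2.28. For postnatal day 14 against 7 they were follicle 0.50, oestrogen −0.12 (reversed), Hedgehog 0.14, kinase inhibitors −0.53, imprinted −0.75, matrix 0.043 (reversed), stress 0.044 and germ oocyte −1.32. Of these Hedgehog, kinase inhibitors, imprinted and stress changed sign too, from −0.18, 0.10, 0.04 and −0.13, none of which was called. For postnatal day 14 against embryonic day 16.5 they were follicle 1.21, Notch 0.10, S −0.25, G2 and M 0.022, kinase inhibitors −0.72, matrix 0.64 (−0.01 before, not called) and germ oocyte 1.06 (reversed).

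With each library clustered on its own, the Esr2 share at postnatal day 14 was 77.3% and Esr1 20.2 CPM, and the Esr1 log2 ratio was −0.018 against postnatal day 7 and −0.29 against the embryo; 3 germ-cell-like cells with 21 Esr1 UMIs had joined, and the other 93 cells were at 9.99 CPM. Germ oocyte medians were 0.77 for postnatal day 7 against the embryo, and 1.99 and 2.17 (both reversed) for postnatal day 14 against 7 and the embryo. For postnatal day 14 against 7 Notch was −0.086 and G2 and M −0.55; against the embryo G2 and M was 0.72, kinase inhibitors −0.82 and germ meiotic −0.85.

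A pseudocount of 1 CPM widens and one of 50 CPM narrows log ratios by construction. With 1 CPM, postnatal day 7 against the embryo gave follicle 1.84, WNT −2.15, Notch 1.37, G2 and M 1.57, kinase inhibitors −1.33, imprinted −2.56, germ meiotic −3.17 and germ oocyte 1.00. Postnatal day 14 against 7 gave follicle 1.14, Notch −0.71, G2 and M −0.95 and germ oocyte −1.66. Postnatal day 14 against the embryo gave follicle 3.14, WNT −2.36, kinase inhibitors −2.59, germ meiotic −3.37 and germ oocyte −2.15. With 50 CPM, postnatal day 7 against the embryo gave follicle 0.75, WNT −0.64, Notch 0.26, G2 and M 0.61, imprinted −1.36, TGF-β −0.19 and germ meiotic −0.32. Postnatal day 14 against 7 gave follicle 0.38, Notch −0.081, S −0.35, G2 and M −0.38 and germ oocyte −0.15. Postnatal day 14 against the embryo gave follicle 0.85, WNT −0.61, Notch 0.15, kinase inhibitors −0.51, imprinted −1.06, germ meiotic −0.31 and germ oocyte −0.20.

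Without a low count filter, more undetected members entered: oestrogen 0, Notch 0.32 and germ oocyte 0.067 for postnatal day 7 against the embryo; follicle 0.66, oestrogen 0.053 and germ oocyte −0.071 for postnatal day 14 against 7; kinase inhibitors −0.63 and germ oocyte 0 for postnatal day 14 against the embryo. With 30 UMIs required, fewer members remained, and the medians in the same order were Notch 1.25 and germ meiotic −1.86, then follicle 0.66 and Notch −0.69, then kinase inhibitors −1.80 and germ meiotic −2.07.

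The mean of CPM over cells gave Esr1 at 15.5 CPM in the embryo, follicle 1.17 and matrix −0.60 for postnatal day 14 against 7, and imprinted −2.11, matrix −0.40 and stress −0.24 (0.07 before, not called) for postnatal day 14 against the embryo. Without Upk3b or Upk1b UMIs, Esr1 was 17.2 CPM in the embryo, its log2 ratio for postnatal day 14 against the embryo −0.69 in place of −1.32, and kinase inhibitors −1.96 for postnatal day 14 against the embryo. With list genes kept in the clustering, G2 and M was 1.54 for postnatal day 7 and 0.68 for postnatal day 14 against the embryo, and kinase inhibitors −1.84 for the latter. With the main cluster of each library only, G2 and M was −1.07 for postnatal day 14 against 7, and the Esr1 log2 ratio for postnatal day 14 against the embryo was −2.01. With clusters 3 and 5 added, the stroma-like G2 and M median was 0.81 (reversed) for postnatal day 7 and −0.097 for postnatal day 14 against the embryo, and the S phase median −0.0053 and −0.64.

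Shares of cells with a UMI depend on depth. Not thinned, Esr1 was in 25.6%, 24.7% and 11.7% of cells at the 3 ages, Esr2 in 69.7% and 64.9% after birth, and both in 19.1% and 7.45%. Thinned to 2000 UMIs, Esr2 was in 14.6% and 19.1%, and both in 0% at postnatal day 7.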

Other observations

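All genes and cells described here were chosen after their values were seen, and none of the values was tested.

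The Hedgehog ligand genes Ihh and Dhh and the target genes Gli1, Ptch1 and Hhip had different levels in different classes. Ihh was at 0.548, 32.5 and 185 CPM in granulosa-like cells at the 3 ages and Dhh at 0.548, 35.0 and 27.7 CPM, while Ihh in stroma-like cells was at 0.532, 0.483 and 2.17 CPM. Gli1, a transcription factor that Hedgehog signals induce, was at 2.19, 2.03 and 1.21 CPM in granulosa-like cells and 8.51, 25.1 and 25.6 CPM in stroma-like cells. In the unnamed clusters it was at 43.4 and 50.1 CPM (cluster 3) and 27.6 and 39.9 CPM (cluster 5) at postnatal days 7 and 14. Ptch1, the receptor and a target, was at 34.5, 91.8 and 79.6 CPM in granulosa-like cells and 12.2, 129 and 152 CPM in stroma-like cells, and in cluster 5 it was at 263 and 296 CPM. Smooth-muscle-like cells had Ptch1 at 78.6 and 260 CPM and Hhip at 36.3 and 202 CPM at postnatal days 7 and 14. Theca-like cells at postnatal day 14 had Gli1 at 5.72 CPM and Ptch1 at 53.8 CPM, and the steroid genes that mark the class, among them Cyp17a1 at 1620.0 CPM and Lhcgr at 238 CPM.

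Greb1, an oestrogen-induced gene in other tissues, differed between ages in several classes. It was at 91.4, 186 and 353 CPM in granulosa-like cells, 17, 46.3 and 141 CPM in stroma-like cells and 221 CPM in theca-like cells at postnatal day 14. Cluster 3 had Mki67 at 213 and 189 CPM at postnatal days 7 and 14. In germ-cell-like cells Ooep, a maternal factor of the egg, was at 4.61 CPM in the embryo, 2692 CPM at postnatal day 7 and 3357 CPM in the 3 cells of postnatal day 14; Uchl1 was at 43.3 and 2005 CPM at the earlier ages.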
